A study of Mus musculus with 38 samples.

How the data were processed

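RNA-seq was measured in 38 sorted samples of mouse cells in 9 groups, and the gene-level tables of the authors were the starting point. Per the labels' protocols, cells were sorted into lysis buffer, RNA was purified with RNeasy Plus Micro columns, cDNA was made with SMART-seq v4 and libraries with Nextera XT. Per the submitters' processing notes, Salmon 1.8.0 and the GRCm38 build were used. How transcripts were summed to genes, the annotation and the method of the size factors are not given in the sources used here. The deposited values are a signal per gene, normalized counts on a linear scale, in 3 tables that were treated as normalized separately. The tables are those of the ileal epithelium (8 libraries, 21045 genes listed), of the reporter CD8 T cells (18 libraries) and of the CD36 and LepR sorts (12 libraries), the latter pair with 35663 genes each. The epithelial table lists 14618 fewer genes, and why is not given in the sources used here. A further 6 columns of per-sample values, which match no listed sample, were not used. Gene symbols are those of the tables, and coordinates come from GENCODE vM21 (GRCm38), matched by gene identifier for 20970 of 21045 and 35349 of 35663 identifiers.

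Whole reads were recovered by dividing each value by the smallest value above 0 in its library, which assumes that this value stands for 1 read; 100% of values came out whole within a tolerance of 0.01. The recovered totals gave the depth of each library. A fold against a group without reads is a lower bound, set at 3 reads per library at the largest such level in that group. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where a gene had 1 to 3 reads in a group, only levels are given. Near-identical copies (Sprr2a1, Sprr2a2 and Sprr2a3; Hba-a1 and Hba-a2; Gzmd and Gzme; H2bc14 and H2bc3) can share reads, and their separate values are uncertain.

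Values were tested as log2(value + 1) with limma 3.58.1 (R 4.3.3), with a trended, robust empirical Bayes fit and two-sided moderated tests. All groups of a table entered its fit, so that they shared a single estimate of the spread, with the group as the only factor. Genes were kept where the value was at least 10 in at least as many libraries as the smallest group of the fit held. P-values were adjusted by Benjamini-Hochberg over the genes tested, and calls were made at an adjusted p under 0.05. Normalized counts had been assumed when the design was set, so the planned test stood. As an addition, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. In the order in which the comparisons are reported, edgeR called 1632, 44, 6003, 5217, 281, 993, 18 and 1550 genes and DESeq2 called 2506, 263, 6625, 6029, 880, 2171, 873 and 2426.

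Before the data were examined, 45 gene lists were fixed, of pathways and of markers of the sorted cells and of others that a gate could hold. Each was tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, if at least 5 of its genes were tested. In the same order of comparisons, 26, 33, 33, 33, 33, 30, 30 and 30 lists were tested, 16, 18, 17, 18, 7, 15, 6 and 15 were called with the preset correlation, and 2, 4, 3, 5, 1, 5, 0 and 0 with an estimated one. Counts of members are given over all genes and adjusted over the list alone. The signature carried from the reporter tumor cells to the CD36 and LepR sorts took called genes with a log2 fold change of at least 1, and its 6 set tests were adjusted together.

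Genes were named by a rule fixed before the data were examined: the sorted or reported markers, whatever their values; the 10 genes with the largest rises and the 10 with the largest falls (5 and 5 in tumor against mLN, mLN against spleen and the comparisons with LepR single-positive cells) among those called, with a mean of at least 50 in the higher group, no overlap between the groups and an informative symbol; and up to 4 members with the smallest adjusted p of each list described. Outside that rule, Fos, Lgr5, Reg3b, Reg3g, Cd163, Ifi203, Ddx58, Slc2a3, Cx3cr1 (double-positive against double-negative), Tnf, Zeb2, Isg20 and Sdha (against LepR single-positive) were named after their values were seen, to complete small counts. 

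The groups share replicate numbers, and whether these pair the samples was checked by correlating the libraries' deviations from their group means. Between double-positive and single-positive tumor libraries of the reporter mice, the numbers in the library names did: all 5 pairs lay above 0.1, from 0.12 to 0.40, with a mean of 0.23 against -0.05 for other pairings, and each correlated best with its own number. No other comparison met that standard. The pair block is a fit of these 2 groups with that number as a block.

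The fit was tested on data simulated from the libraries' means and spread, with 96 to 100 changed genes per fold. Of genes changed 4-fold, it recovered 19.4%, 61.0%, 55.0%, 59.0%, 51.0%, 34.3%, 34.3% and 33.0% in the same order. For 2-fold changes it recovered 2.08%, 13.1%, 8.00%, 7.00%, 10.0%, 4.08%, 7.07% and 8.08%, so many would be missed where as few genes change. It called 4, 6, 6, 11, 9, 2, 3 and 9 unchanged genes, mostly over 0.05 of its calls. Alternatives were pseudocounts of 0.5 and 8, no filter, a mean filter of at least 50, TMM and quantile scaling, library weights, a fit of only the groups compared, each library left out, and blocks by replicate number. Figures used matplotlib 3.10.9 (Python 3.11.15). Sequence reads were not analysed.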

Results

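RNA-seq libraries were made from 38 sorted mouse cell samples in 9 groups. The reporter mice carry CyCLoPs, which the series title presents as a way to label cytokine activity in living animals. Ileal epithelial cells of SFB-colonized IL-17A reporter mice were sorted as GFP-high (n = 4) or GFP-negative (n = 4). CD8 T cells of IFNg reporter mice that carried TagBFP alone came from spleen (n = 4), mesenteric lymph node (mLN, n = 3) and tumor (n = 6), and a further tumor group carried both TagBFP and GFP (n = 5). Tumor CD8 T cells of wild-type mice were sorted as negative for both CD36 and LepR (n = 3), positive for LepR alone (n = 4) or positive for both (n = 5). The labels do not say which event each fluorescent protein marks, so groups are named by fluorescence. Values are normalized counts (mean ± SD over a group's n libraries). Log2 fold changes are differences of mean log2(value + 1), which can understate changes of low values or exceed the log2 ratio of the means.

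Depth ranged from 17.1 to 59.7 M recovered reads in the epithelial libraries, from 7.89 to 79.3 M in the reporter CD8 T cell libraries and from 22.9 to 41.1 M in the CD36 and LepR sorted libraries. The shallowest library, spleen replicate 2 with 7.89 M reads, had a mean correlation of 0.806 with the other spleen libraries, whose own means lay between 0.876 and 0.885. Within groups, no pair of libraries agreed within sampling noise: over 65 pairs the chi-square statistic per gene lay between 49.8 and 692. Each comparison lies within 1 table and 1 batch label, and the tables were treated as normalized separately, so no test compares levels across them. The labels do not state that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. All adjusted p-values are from limma with Benjamini-Hochberg adjustment, and set tests are from limma's camera with a preset correlation unless an estimated one is named.

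In the ileum, the comparison asked how epithelial cells with a high GFP signal differ from GFP-negative cells. Of 31 measured genes of nutrient absorption 30 rose (31 adjusted over the list alone), with a median log2 fold change of 3.13. Fabp2, a fatty acid binding protein of enterocytes, stood at 413463 ± 147389 against 9301 ± 3002 (log2 fold change 5.47, adjusted p = 7.08e-06). Slc5a1, the sodium-glucose cotransporter, stood at 99557 ± 17341 against 9806 ± 2541 (3.37, adjusted p = 1.82e-05), and the neutral amino acid transporter Slc6a19 at 38216 ± 12788 against 831 ± 292 (5.52, adjusted p = 1.27e-05). Of 15 measured villus-tip genes 10 rose and 1 fell, over all genes and over the list alone, with a median of 2.46. Apoa1 and Apoa4, apolipoproteins of chylomicrons, rose to 834462 ± 331225 from 9726 ± 4044 (6.46, adjusted p = 7.08e-06) and to 166935 ± 157215 from 807 ± 585 (7.64, adjusted p = 0.000217). The member that fell was Fos, an immediate early transcription factor (-1.16, adjusted p = 0.00768). The absorption list moved up as a set (adjusted p = 1.9e-30, and 0.0445 with an estimated correlation, lost with a pseudocount of 8, 0.0642, and whichever library was left out, 0.0539 to 0.0913), as did the villus-tip list (adjusted p = 7.51e-08), which lost its call with an estimated correlation (adjusted p = 0.0816). Epcam, the epithelial surface marker, rose from 27167 ± 6741 to 68716 ± 20805 (1.33, adjusted p = 0.00454), a call lost with quantile normalization.

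Several IL-17 target genes were far higher in GFP-high cells. Ccl20, a chemokine gene at chromosome 1, 83116766 to 83119167 (GRCm38), stood at 6026 ± 3252 against 82.9 ± 43.0 (log2 fold change 6.14, SE 0.56, adjusted p = 0.000104). Nos2, the inducible nitric oxide synthase gene at chromosome 11, 78920787 to 78960254, stood at 13036 ± 5644 against 278 ± 185 (5.72, SE 0.54, adjusted p = 0.000124). Ubd, a ubiquitin-like modifier, rose by 6.43 (adjusted p = 0.000726) and Duox2, a hydrogen peroxide-producing oxidase, by 1.64 (adjusted p = 0.000625). In all, 11 of 23 measured genes of IL-17 receptor signalling and its targets rose (13 up and 1 down adjusted over the list alone), and 1 fell without GFP-high replicates 1 or 3 or GFP-negative replicate 2. The median was 1.21 (set test adjusted p = 3.24e-05, and adjusted p = 0.0746 with an estimated correlation). Il17rc, a receptor subunit for IL-17A at chromosome 6, 113471427 to 113483140, rose from 8375 ± 2379 to 14454 ± 1776 (0.82, adjusted p = 0.0233). That call was lost with quantile normalization, with library weights, and without GFP-high replicate 4 (adjusted p = 0.0555), GFP-negative replicate 2 (adjusted p = 0.0606) or GFP-negative replicate 3 (adjusted p = 0.0689). Il17ra, the other subunit, stood at 1268 ± 624 against 1985 ± 476 (-0.79, adjusted p = 0.21), and Il17a is listed at 0 in all 8 libraries.

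Of 14 measured antimicrobial REG, lectin and small proline-rich genes 6 rose, over all genes and over the list alone. Sprr2a2, an epithelial small proline-rich protein gene, reached 346035 ± 16601 against 7662 ± 2829 (5.57, adjusted p = 3.31e-06). Its near-identical copies Sprr2a1 (5.33) and Sprr2a3 (5.76) also rose, and reads could be split between the copies. Reg3a, an antimicrobial lectin, rose by 1.93 (adjusted p = 0.00521), and Reg3b and Reg3g made up the 6; both lost their calls with quantile normalization and without any library except GFP-high replicate 3 or GFP-negative replicate 2 (adjusted p = 0.0521 to 0.0825). The list's median was 0.03 and turned negative, to -0.34, -0.35 and -0.51, without GFP-high replicate 3 or GFP-negative replicates 1 or 2, and lay between 0.40 and 0.59 without any of the others. Its set test (adjusted p = 0.0189) was lost with an estimated correlation (adjusted p = 0.0986) and with quantile normalization (adjusted p = 0.152).

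Some antigen presentation and interferon genes were higher in GFP-high cells. Of 8 measured MHC class II genes 6 rose, over all genes and over the list alone (median 1.89; set test adjusted p = 1.02e-05, and adjusted p = 0.128 with an estimated correlation). H2-Aa, an MHC class II alpha chain, stood at 12645 ± 2513 against 1065 ± 463 (3.64, adjusted p = 4.73e-05), and Cd74, the invariant chain, at 84589.7 ± 21306 against 19557 ± 6168 (2.13, adjusted p = 0.000387). The only 4 dendritic cell markers measured in this table, H2-Aa, H2-Ab1, H2-Eb1 and Cd74, are also members of the class II list, and all 4 rose. Of 26 interferon gamma response genes 9 rose (9 up and 1 down adjusted over the list alone), led by B2m, the class I light chain (90555 ± 22501 against 15668 ± 1481; 2.50, adjusted p = 2.49e-05). Their median of 0.78 came to 1.39, 1.21 and 1.19 without GFP-high replicates 1 or 3 or GFP-negative replicate 2 (set test adjusted p = 3.81e-05, and adjusted p = 0.0746 with an estimated correlation). Of 25 type I interferon response genes 10 rose (14 up and 1 down adjusted over the list alone), among them Isg15 (2.79, adjusted p = 0.000934) and Irf7 (1.86, adjusted p = 0.00119). The median of that list was 2.03 (set test adjusted p = 4.3e-06, and adjusted p = 0.055 with an estimated correlation).

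Some secretory, stem and dividing-cell transcripts were lower in GFP-high cells. Of 17 goblet cell genes 10 fell (12 adjusted over the list alone; median -2.62), among them Zg16, a mucus protein, at 57929 ± 21469 against 304542 ± 139764 (-2.32, adjusted p = 0.00273) and Tff3, a trefoil peptide, at 26661 ± 12622 against 140390.0 ± 61099 (-2.40, adjusted p = 0.00294). Of 18 enteroendocrine genes 9 fell, over all genes and over the list alone (median -3.17; 5 fell without GFP-negative replicate 4), among them Cck (-2.88, adjusted p = 0.00138) and Sct (-1.55, adjusted p = 0.0119), which encode gut hormones. Isl1, an endocrine transcription factor, had no read in GFP-high cells and was at least 34.3-fold lower there, at a floor of 3 reads per library. Of 43 cell cycle genes 21 fell (33 adjusted over the list alone; median -3.91), such as Aurka, a mitotic kinase (7.51 ± 7.60 against 816 ± 316; -7.23, adjusted p = 0.00267). The goblet list (adjusted p = 1.74e-05), the enteroendocrine list (adjusted p = 3.81e-05) and the cell cycle list (adjusted p = 1.2e-10) moved down as sets. With an estimated correlation the adjusted p was 0.239, 0.0445 and 0.1 in that order, so the enteroendocrine list alone kept its call. It lost it with a pseudocount of 8 (adjusted p = 0.0642), with quantile normalization (adjusted p = 0.0805) and whichever library was left out (adjusted p = 0.0539 to 0.0913).

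Of 13 intestinal stem cell genes 5 fell, 8 with a pseudocount of 8, 3 without GFP-high replicate 2 and 2 without GFP-negative replicate 3 or 4 (9 adjusted over the list alone; median -3.96, set test adjusted p = 0.00103, and adjusted p = 0.131 with an estimated correlation). They were Olfm4, a crypt-base marker at 1808 ± 533 against 19737 ± 4955 (-3.46, adjusted p = 3.26e-05), Prom1 (-1.75, adjusted p = 0.00792), Ascl2 (-6.60), Sox9 (-2.30) and Lgr5 (-5.28). Ascl2 lost its call without GFP-negative replicate 3 (adjusted p = 0.0506) or 4 (adjusted p = 0.0536), and with edgeR. Sox9 lost it without GFP-high replicate 2 or 4 or any GFP-negative replicate (adjusted p = 0.0515 to 0.0885), and edgeR did not call it. Lgr5 lost its call without any library except GFP-negative replicate 1 (adjusted p = 0.0551 to 0.129). It also lost it with a pseudocount of 0.5, without a filter, with the mean filter, TMM, quantile normalization, library weights and edgeR (adjusted p = 0.0527 to 0.143). Of 12 tuft cell genes 3 fell, over all genes and over the list alone (median -2.32, and -3.68 without GFP-high replicate 4): Avil, Dclk1 and Cd24a. All 3 lost their calls with edgeR (adjusted p = 0.137, 0.234 and 0.171) and without GFP-high replicates 2 or 4 or GFP-negative replicates 1 or 4. Dclk1 and Cd24a also lost theirs without a filter, with DESeq2 and without GFP-negative replicates 2 or 3, and Cd24a with TMM and without GFP-high replicate 1. The set test (adjusted p = 0.0428, and adjusted p = 0.236 with an estimated correlation) lost its call without GFP-high replicate 2 (adjusted p = 0.0854), GFP-negative replicate 1 (adjusted p = 0.0718) or GFP-negative replicate 2 (adjusted p = 0.0508), with the mean filter (adjusted p = 0.0522) and with quantile normalization (adjusted p = 0.12).

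All 37 measured cytosolic ribosomal protein genes fell, over all genes and over the list alone, by a median of -1.78, and did so too with both other scalings. Rplp0 stood at 9458 ± 2574 against 29835 ± 1125 (-1.70, adjusted p = 0.000356) and Rpl4 at 5402 ± 1099 against 16558 ± 2499.8 (-1.63, adjusted p = 0.000411). Of 22 dissociation and heat shock genes 11 fell (14 adjusted over the list alone; median -1.06), among them Atf3 (-2.01, adjusted p = 0.00122) and Hsp90aa1 (-1.29, adjusted p = 0.0014). The ribosomal list (adjusted p = 4.45e-22) and the dissociation list (adjusted p = 3.39e-05) moved down as sets, and both calls were lost with an estimated correlation (adjusted p = 0.128 and 0.0746).

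Over all genes, 2221 of 10877 tested were called, 1110 higher and 1111 lower in GFP-high cells, and the median log2 fold change of all genes was -0.32, which quantile normalization moved by 0.28 towards 0. The largest rises were in Cyp2d22, Susd2, Gdpd2, Cyp3a11, Aldh4a1, Gml, Pdzk1, Slc5a12, Enpp7 and Egln3, among genes whose groups did not overlap. Cyp3a11, a drug-metabolizing cytochrome P450, stood at 7734 ± 7848 against 6.59 ± 7.66 and Enpp7, the alkaline sphingomyelinase, at 34027 ± 15478 against 262 ± 355 (9.01, adjusted p = 0.00221). Gml had no read in GFP-negative cells and was at least 275-fold higher in GFP-high cells. Among the largest falls, the cell division gene Kif2c was at least 85.8-fold, the endocrine transcription factor Rfx6 at least 71.4-fold and the potassium channel subunit Abcc8 at least 75.9-fold lower.

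**Figure D1:**
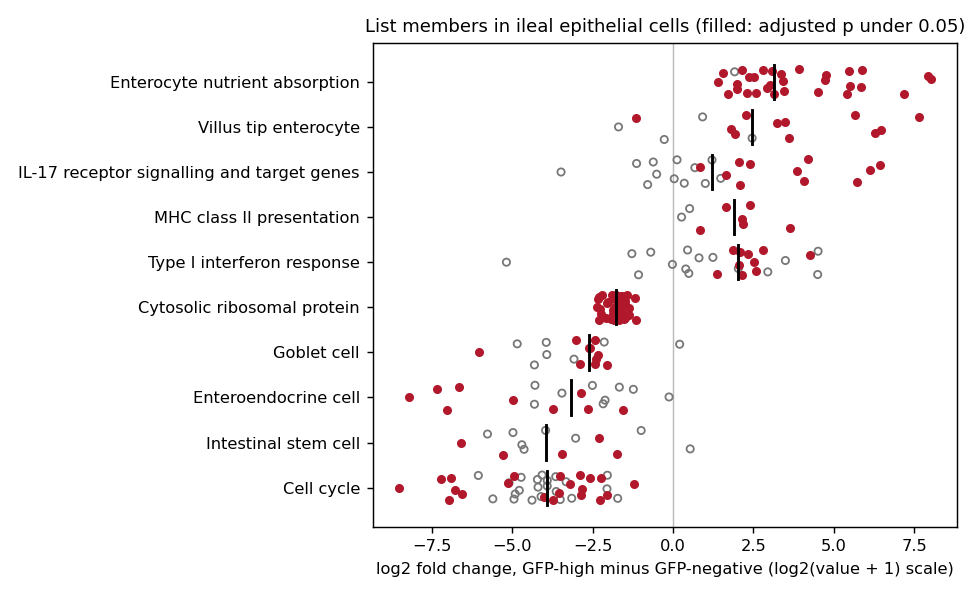
Log2 fold change (GFP-high minus GFP-negative, log2(value + 1) scale, x axis) of each measured member of 10 gene lists (y axis) in ileal epithelial cells; filled points passed limma at an adjusted p under 0.05, open points did not, and bars are list medians. The 31 absorption genes have a median of 3.13 and the 43 cell cycle genes one of -3.91, and all 37 ribosomal protein genes lie below 0.

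In tumors of IFNg reporter mice, libraries labelled as TagBFP and GFP double-positive CD8 T cells were compared with those labelled as positive for TagBFP alone. T cell markers go against both labels: the summed macrophage values were at least 66.3 times the summed T cell values in each library, and Cd8b1 stood at 707 ± 314 against 1053 ± 229.8, against 48538 ± 6524 in spleen. Directions below are those of the libraries so labelled. Cd36, the fatty acid translocase gene at chromosome 5, 17781690 to 17888801 (GRCm38), was higher in double-positive cells, at 9189 ± 6945 against 619 ± 317 (log2 fold change 3.71, SE 0.56, adjusted p = 0.00659). Among the genes that rose with it were Vsig4, a complement receptor (607 ± 616 against 2.04 ± 5.00; 7.97, adjusted p = 0.000197), Cd5l (7.75, adjusted p = 0.0122), Fcna (5.31, adjusted p = 0.00659) and Folr2, a folate receptor (5.10, adjusted p = 0.00838). F7, coagulation factor VII, rose from 435 ± 160.0 to 6209.9 ± 2824 (3.81, adjusted p = 0.000197), and the histone genes H2bc14 (5.15) and H2bc3 (5.08) rose as well. Lower in double-positive cells were Plac8 (-1.87, adjusted p = 0.015) and Ms4a4c (4399 ± 1020.3 against 15747 ± 2897; -1.85, adjusted p = 0.0041). Lepr, the leptin receptor gene at chromosome 4, 101717404 to 101815352, stood at 2884 ± 3598 against 47.5 ± 81.4 and was not called (5.72, adjusted p = 0.16); it was called with library weights, with DESeq2 and without double-positive replicate 2 (adjusted p = 0.00724).

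T cell and effector lists had negative medians in double-positive cells, and few members passed singly. Of 16 T cell markers none passed over all genes (11 at an unadjusted p under 0.05, 10 lower adjusted over the list alone), and their median was -0.70 (set test adjusted p = 1.76e-10, and adjusted p = 0.117 with an estimated correlation). Cd8a stood at 1216 ± 524 against 1658 ± 338 (-0.52, adjusted p = 0.642) and Cd8b1 changed by -0.66 (adjusted p = 0.408). Of 27 cytotoxic effector genes 1 fell (11 adjusted over the list alone; median -0.78, set test adjusted p = 6.43e-10, and adjusted p = 0.0671 with an estimated correlation). That gene was Gzmd, a granzyme with a near-identical copy, Gzme (0.998 ± 1.58 against 74.8 ± 69.6; -4.76, adjusted p = 0.0174). Its call was lost without double-positive replicate 4 (adjusted p = 0.0616), with the pair block (adjusted p = 0.068), with quantile normalization and with edgeR, and 2 genes fell with the pair block, without single-positive replicate 1 or without double-positive replicate 5. With library weights 5 fell, and 4 with only the groups compared. Of 37 interferon gamma response genes none passed, over all genes or over the list alone (9 at an unadjusted p under 0.05), at a median of -0.58 (set test adjusted p = 6.12e-09, and adjusted p = 0.288 with an estimated correlation). With the pair block 8 of 36 fell, and 3 with library weights. Ifng stood at 138 ± 88.8 against 485 ± 187 (-1.90, adjusted p = 0.304); it was called with only the groups compared (adjusted p = 0.0328) and with the block by title (adjusted p = 0.0433). Its receptor genes Ifngr1 (-0.06) and Ifngr2 (-0.03) were not called.

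Of 32 genes of fatty acid uptake and oxidation 3 rose (4 adjusted over the list alone; median 0.27): Cd36, Fabp5, a fatty acid binding protein (4718 ± 961 against 1685 ± 443; 1.51, adjusted p = 0.0265), and Plin2, a lipid droplet protein (41259.7 ± 19893 against 16061 ± 2087; 1.24, adjusted p = 0.0398). Of 25 oxidative stress and ferroptosis genes 1 rose (4 adjusted over the list alone; median 0.37): Hmox1, heme oxygenase (35368 ± 35910.0 against 3834 ± 551; 2.49, adjusted p = 0.0398). Fabp5 lost its call without TagBFP single-positive replicates 1, 2 or 5 (adjusted p = 0.0533, 0.0615 and 0.0557) or double-positive replicate 4 (adjusted p = 0.0922). Plin2 and Hmox1 lost theirs without any single-positive replicate or double-positive replicate 1, 4 or 5 (adjusted p = 0.0533 to 0.125 for Plin2 and 0.0602 to 0.11 for Hmox1), and Hmox1 also with the pair block (adjusted p = 0.0502). Both lost them without a filter (adjusted p = 0.0582 and 0.0651), Plin2 with quantile normalization (adjusted p = 0.054) and Hmox1 with only the groups compared (adjusted p = 0.067). With the pair block, a pseudocount of 8 or without double-positive replicate 2, 2 genes of its list rose, and 5 with library weights. Both lists moved up as sets (adjusted p = 5.66e-07 for each, and 0.0295 and 0.0163 with an estimated correlation), while with the pair block their adjusted p was 0.206 with an estimated correlation. Both estimated calls were lost with only the groups compared (adjusted p = 0.137), and the first with library weights (adjusted p = 0.0503) and without double-positive replicate 4 (adjusted p = 0.0505). Of 24 glycolysis genes none passed over all genes (7 up and 1 down at an unadjusted p under 0.05, 5 up adjusted over the list alone), at a median of 0.26 (set test adjusted p = 6.9e-06, and adjusted p = 0.17 with an estimated correlation). With the pair block 1 rose.

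The ratio of summed macrophage to summed T cell list values was 272 ± 79.2 (SD, n = 5) in double-positive and 106 ± 31.7 (SD, n = 6) in single-positive tumor libraries. It was higher in the double-positive library of all 5 pairs (exact sign-flip p = 0.0625, the lowest that 5 pairs allow; added after the ratios were seen). Of 26 macrophage and monocyte markers none passed, over all genes or over the list alone (6 up and 1 down at an unadjusted p under 0.05), while 3 rose and 1 fell with the pair block and 1 rose without double-positive replicate 2. Their median of 0.16 came to 0.27 without double-positive replicate 1 and to 0.06 without single-positive replicate 6. The set test (adjusted p = 0.00596) was lost with an estimated correlation (adjusted p = 0.337), with quantile normalization (adjusted p = 0.211) and without single-positive replicate 6 (adjusted p = 0.119). Lyz2, lysozyme, stood at 889981 ± 114150.0 against 420705 ± 107786 (1.13, adjusted p = 0.255) and Arg1, arginase, at 228886 ± 109196 against 38325 ± 8292 (2.46, adjusted p = 0.289); both were called with the pair block (adjusted p = 0.029 and 0.0184), the block by title and only the groups compared, and Arg1 with a pseudocount of 8. Of 13 dendritic cell markers none passed over all genes (8 at an unadjusted p under 0.05, 7 lower adjusted over the list alone; median -1.46, set test adjusted p = 5.66e-07, and 0.0297 with an estimated correlation). With the pair block 4 fell, and the adjusted p with an estimated correlation was 0.206. That call was also lost with library weights (adjusted p = 0.0503), only the groups compared (adjusted p = 0.137) and without double-positive replicates 1, 2 or 4 (adjusted p = 0.065, 0.0541 and 0.0505). Of 5 adipocyte markers 1 rose, Cd36, and 3 did adjusted over the list alone (median 1.35, set test adjusted p = 0.000177, and 0.0163 with an estimated correlation).

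Over all genes, 60 of 14626 tested were called, 42 higher and 18 lower in double-positive cells, with 1145 at an unadjusted p under 0.05. Libraries with the same number in their names deviated together, and with that number as a block 204 genes were called, 114 higher and 90 lower, of which 42 were among the 60. The count was 22 without double-positive replicate 4, 29 without double-positive replicate 5 and 39 without double-positive replicate 1. It was 34, 29, 30 and 28 without single-positive replicates 1, 2, 3 and 5.

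Tumor libraries labelled as TagBFP single-positive CD8 T cells were then compared with those of the spleen. Tumor libraries held few T cell transcripts and many myeloid ones. All 16 T cell markers fell, over all genes and over the list alone, by a median of -4.19 (set test adjusted p = 6.05e-19, and 0.042 with an estimated correlation). The estimated call was lost with the mean filter (adjusted p = 0.0562), library weights (adjusted p = 0.105), only the groups compared (adjusted p = 0.0767) and without spleen replicates 2, 3 or 4 (adjusted p = 0.0927, 0.0575 and 0.0526). Cd8b1, the CD8 beta chain gene at chromosome 6, 71322788 to 71337494 (GRCm38), stood at 1053 ± 229.8 against 48538 ± 6524 (log2 fold change -5.54, SE 0.26, adjusted p = 2.28e-11), and Cd8a at 1658 ± 338 against 25010.5 ± 6245 (-3.90, adjusted p = 2.64e-09). Lck, the T cell receptor kinase, fell by 4.34 on the log2 scale (adjusted p = 6.21e-10). All 19 naive and memory T cell genes fell, over all genes and over the list alone (median -3.66, set test adjusted p = 1.07e-14, and 0.0188 with an estimated correlation, lost without spleen replicate 2, 0.0547). Among them was Tcf7, a transcription factor of naive and memory cells (146 ± 81.6 against 14389 ± 3309; -6.80, adjusted p = 1.59e-08).

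Of 26 macrophage and monocyte markers 23 rose and 1 fell (24 and 1 adjusted over the list alone; median 5.06, set test adjusted p = 6.05e-19, and 0.0127 with an estimated correlation, lost with only the groups compared, 0.0512). Spi1, the myeloid transcription factor PU.1, stood at 16013 ± 3033 against 474 ± 107 (5.08, adjusted p = 1.37e-12), and Fcgr3, an Fc receptor, at 63403 ± 9902 against 647 ± 189.8 (6.66, adjusted p = 1.48e-12). Arg1 rose from 2.56 ± 4.30 to 38325 ± 8292 (14.06, adjusted p = 4.72e-10). The complement receptors C5ar1 and C3ar1 had no read in spleen and were at least 2448-fold and 1984-fold higher in tumor. The same held for Trem2, a lipid-sensing receptor of macrophages, at least 672-fold higher, and for Ptgs2, the inducible cyclooxygenase, at least 1302-fold. The member that fell was Cd163, a scavenger receptor (17.8 ± 28.7 against 388 ± 373; -5.15, adjusted p = 0.0336), a call lost without a filter and without spleen replicates 1 or 4 (adjusted p = 0.0839 and 0.092) or tumor replicates 1, 2 or 3 (adjusted p = 0.067, 0.0534 and 0.0678). Of 12 neutrophil markers 10 rose, over all genes and over the list alone, with a median of 6.43 (5.65 with genes without a spleen read at their bound; set test adjusted p = 3.04e-05, and adjusted p = 0.0725 with an estimated correlation, called without a filter, 0.0231, and with quantile normalization, 0.0332). The macrophage to T cell ratio in spleen was 0.178 ± 0.028 (SD, n = 4).

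Metabolic and interferon genes moved with them. Of 24 glycolysis genes 18 rose and 1 fell, over all genes and over the list alone (median 2.02, set test adjusted p = 1.18e-07, and adjusted p = 0.0794 with an estimated correlation, called without a filter, 0.0263, and with quantile normalization, 0.0332). Among them was Pkm, pyruvate kinase, at 144056 ± 13083 against 25144 ± 4010.4 (2.53, adjusted p = 4.07e-11). The exception was Slc2a3, a glucose transporter (-1.58, adjusted p = 0.00393), and 3 fell without spleen replicate 2. Of 24 cholesterol biosynthesis and uptake genes 17 rose (18 adjusted over the list alone; median 1.41, set test adjusted p = 1.02e-05, and adjusted p = 0.217 with an estimated correlation). Of 33 type I interferon response genes 26 rose and 2 fell (27 and 2 adjusted over the list alone; median 1.75, set test adjusted p = 4.77e-05, and adjusted p = 0.467 with an estimated correlation). Irf7 rose by 2.12 (adjusted p = 6.62e-06). The members that fell were Ifi203 (1380.2 ± 450.1 against 2925 ± 1751) and Ddx58 (2102 ± 436 against 3706 ± 1091). These calls were lost without spleen replicate 2 (adjusted p = 0.137) or tumor replicates 1, 5 or 6 (adjusted p = 0.0588, 0.0534 and 0.072), without a filter or with library weights for Ifi203, and without spleen replicates 3 or 4 (adjusted p = 0.061 and 0.0594) for Ddx58. Ifngr2, an interferon gamma receptor chain, rose from 929 ± 389 to 8389 ± 1700.2 (3.24, adjusted p = 1.65e-08) and Ifngr1 by 0.68 (adjusted p = 0.00676, lost with quantile normalization). Ifng itself stood at 485 ± 187 against 539 ± 507 (0.26, adjusted p = 0.782), Cd36 at 619 ± 317 against 274 ± 187 (1.20, adjusted p = 0.115) and Lepr at 47.5 ± 81.4 against 8.24 ± 7.30 (0.84, adjusted p = 0.71). Of 37 ribosomal protein genes 35 fell (36 adjusted over the list alone; set test adjusted p = 1.07e-10, and adjusted p = 0.505 with an estimated correlation), and their median of -1.44 was -0.75 without spleen replicate 2.

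Over all genes, 6225 of 14626 tested were called, 3618 higher and 2607 lower in tumor. Quantile normalization moved the median of all genes by -0.33, from 0.15 to -0.18, and the split to 2968 higher and 3796 lower.

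Against the mLN, tumor libraries so labelled differed in the same lists. All 16 T cell markers (median -4.24, set test adjusted p = 5.8e-19, and 0.0282 with an estimated correlation) and all 19 naive and memory genes (median -3.94, set test adjusted p = 5.01e-15, and 0.0172 with an estimated correlation) fell, over all genes and over each list alone. Of 26 macrophage markers 25 rose, over all genes and over the list alone (median 7.69, set test adjusted p = 1.87e-25, and 0.00315 with an estimated correlation). Cd14, the lipopolysaccharide co-receptor, stood at 51234 ± 14736 against 42.1 ± 12.3 (10.19, adjusted p = 7.12e-13), while S1pr1, the receptor for lymph node exit, stood at 367 ± 153 against 20059 ± 2973 (-5.89, adjusted p = 3.54e-08). Thbs1, thrombospondin, had no read in the mLN and was at least 17149.9-fold higher in tumor, and C5ar1 at least 7196-fold. Of 12 neutrophil markers 10 rose (12 adjusted over the list alone), with a median of 7.47 (7.30 with genes without an mLN read at their bound; set test adjusted p = 2.95e-06, and 0.0282 with an estimated correlation). Among them was Csf3r, the G-CSF receptor (3479 ± 1219 against 29.5 ± 32.0; 7.33, adjusted p = 1.63e-06). With an estimated correlation, these 4 lists lost their calls with only the groups compared (adjusted p = 0.239, 0.0693, 0.0882 and 0.245 in this order). The T cell and neutrophil lists lost theirs with library weights (adjusted p = 0.0839 and 0.112) and the latter with a pseudocount of 8 (adjusted p = 0.0758). The macrophage to T cell ratio in the mLN was 0.0905 ± 0.00786 (SD, n = 3).

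Ifngr2 was again higher in tumor (8389 ± 1700.2 against 1013 ± 248; 3.05, adjusted p = 1.24e-07). Ifngr1 rose by 0.75 (adjusted p = 0.00756), a call lost with quantile normalization and without mLN replicate 1 (adjusted p = 0.0675). Cd36 rose from 148 ± 84.9 to 619 ± 317 (2.12, adjusted p = 0.0162), a call lost without mLN replicate 3 (adjusted p = 0.135). Ifng stood at 485 ± 187 against 769.7 ± 912 and Lepr at 47.5 ± 81.4 against 4.24 ± 2.95, and neither was called (adjusted p = 0.929 and 0.528), except Lepr with DESeq2 (adjusted p = 0.0451). Of 14626 genes 5481 were called, 3269 higher and 2212 lower in tumor, which became 2700 higher and 3442 lower after quantile normalization moved the median of all genes by -0.34.

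**Figure D2:**
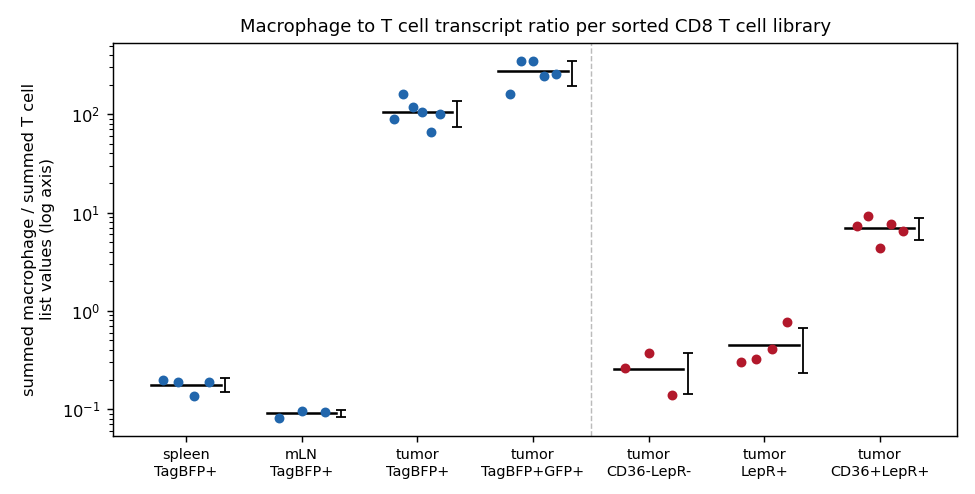
Ratio of the summed values of the macrophage and monocyte list to those of the T cell list (log axis) in each library of the 7 CD8 T cell groups; points are libraries, horizontal bars group means and error bars 1 SD, and the dashed line parts the 2 separately normalized tables. All 11 tumor libraries of the reporter mice lie at 66.3 or above, while spleen and mLN libraries lie below 1.

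Single-positive cells of the mLN and spleen were compared next. Some macrophage and blood cell markers were higher in spleen: 12 of 26 macrophage markers were lower in the mLN (15 adjusted over the list alone; median -1.83, set test adjusted p = 4.21e-15, and 0.0327 with an estimated correlation). The estimated call was lost without spleen replicates 1, 2 or 4 (adjusted p = 0.0723, 0.125 and 0.116), with library weights (adjusted p = 0.0542), with the mean filter (adjusted p = 0.0508) and with only the groups compared (adjusted p = 0.218, 0 genes called). Mrc1, the mannose receptor, stood at 23.2 ± 22.7 against 1057 ± 440.5 (-6.51, adjusted p = 0.000457) and C1qc, a complement component, at 382 ± 275 against 2604 ± 733 (-2.99, adjusted p = 0.000617). Of 10 erythroid and platelet markers 5 were lower in the mLN (6 adjusted over the list alone), with a median of -6.25 (-5.53 with genes without an mLN read at their bound; set test adjusted p = 9.63e-10, and adjusted p = 0.164 with an estimated correlation). Ppbp, a platelet chemokine with no read in the mLN, was at least 55.6-fold lower there, and Pf4 fell to 12.5 ± 14.9 from 81.8 ± 35.6 (-3.19, adjusted p = 0.00756). The hemoglobin genes Hbb-bs (-11.10, adjusted p = 0.0441), Hba-a2 and Hba-a1 were the others, the last pair being near-identical copies. Hbb-bs lost its call without mLN replicates 1, 2 or 3 (adjusted p = 0.139, 0.0711 and 0.167) or spleen replicates 1 or 3 (adjusted p = 0.135 and 0.0734), as did the other hemoglobin genes, which left 2 calls. With edgeR all 3 lost theirs, without a filter Hbb-bs and Hba-a1, and with a pseudocount of 8 Hba-a1.

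Type I interferon genes had a positive median in the mLN. None of 33 passed over all genes (22 at an unadjusted p under 0.05, 16 higher adjusted over the list alone), at a median of 1.24 (set test adjusted p = 1.08e-13, and adjusted p = 0.194 with an estimated correlation). The count was 10 with library weights, 4 with quantile normalization, 3 with the mean filter and 1 with a pseudocount of 8. It was 5 without mLN replicate 2 or spleen replicate 4 and 3 without spleen replicate 2 or 3, and the set was called with an estimated correlation without mLN replicate 2 (adjusted p = 0.0151). Ifit3 stood at 5578 ± 3169 against 1499 ± 612 (1.76, adjusted p = 0.0508) and was called by edgeR and DESeq2, with library weights, the mean filter and quantile normalization, and without mLN replicate 2 (adjusted p = 0.00562) or spleen replicate 4 (adjusted p = 0.0352). Il1rn, the interleukin 1 receptor antagonist, stood at 62.3 ± 9.57 in the mLN and at 0.151 ± 0.303 in spleen (adjusted p = 1.31e-05). Cd8a, Cd8b1, Ifng, Ifngr1, Ifngr2, Cd36 and Lepr were not called. Of 14626 genes 307 were called, 34 higher and 273 lower in the mLN, with 1717 at an unadjusted p under 0.05, and 186 were called without mLN replicate 2. Fitted on the mLN and spleen libraries alone, which left 12544 genes to test, 2 genes were called, none of those named here, and 899 had an unadjusted p under 0.05, against 281 calls with edgeR and 880 with DESeq2.

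In tumors of wild-type mice, libraries labelled as CD36 and LepR double-positive CD8 T cells were compared with double-negative ones. Groups keep their labels, which low Lepr RNA cannot test. Cd36 itself had no read in double-negative cells and stood at 1189 ± 796 in double-positive cells, at least 416-fold higher (adjusted p = 0.00227). Lepr stood at 17.8 ± 30.5 against 10.6 ± 4.25 and was not called (-0.47, adjusted p = 0.849). Ifngr2 was higher (5046 ± 1432 against 534 ± 395; log2 fold change 3.50, SE 0.52, adjusted p = 0.000828). Ifng fell less than the T cell list (5429 ± 447 against 8702 ± 1422; -0.67, adjusted p = 0.0198), a call lost with library weights and without double-negative replicates 2 or 3 (adjusted p = 0.0577 and 0.0976). Of 25 macrophage and monocyte markers 24 rose, over all genes and over the list alone (median 4.23, set test adjusted p = 3.36e-25, and 0.0467 with an estimated correlation). All 5 sets called here with an estimated correlation lost that call with only the groups compared (adjusted p = 0.123), without any of the double-negative replicates (adjusted p = 0.071 to 0.131) and without double-positive replicates 1, 4 or 5 (adjusted p = 0.0502 to 0.077). The macrophage, cytotoxic and oxidative stress sets also lost it with TMM (adjusted p = 0.0501), the latter pair with library weights and the cytotoxic set with quantile normalization (adjusted p = 0.229). Spi1 stood at 12742 ± 1328 against 847 ± 89.4 (3.91, adjusted p = 2.47e-06), Arg1 at 29469 ± 16839.5 against 465 ± 133 (5.85, adjusted p = 9.02e-06) and Ctss, cathepsin S, at 120397 ± 25186 against 8933 ± 4207 (3.86, adjusted p = 2.32e-05). Of 12 dendritic cell markers 7 rose (9 adjusted over the list alone; median 4.33, set test adjusted p = 5.25e-08, and 0.0369 with an estimated correlation), among them Cd74 (363326 ± 146888 against 21470.2 ± 6105; 4.01, adjusted p = 2.55e-05). The macrophage to T cell ratio was 6.99 ± 1.77 (SD, n = 5) in double-positive and 0.258 ± 0.116 (SD, n = 3) in double-negative libraries.

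T cell transcripts fell by a similar amount across the list: 15 of 16 markers fell, over all genes and over the list alone, by a median of -1.24 with an interquartile range of 0.285 (set test adjusted p = 1.65e-20, and 0.0369 with an estimated correlation). Cd8a stood at 25443 ± 4255 against 54168 ± 8411 (-1.10, adjusted p = 0.00134) and Cd3e at 18135 ± 3268 against 49587 ± 8196 (-1.46, adjusted p = 8.19e-05). Of 27 cytotoxic effector genes 3 rose and 12 fell, 7 without double-positive replicate 2 (4 and 15 adjusted over the list alone; median -0.88, set test adjusted p = 3.02e-05, and 0.0467 with an estimated correlation). Gzmb, granzyme B, stood at 22947 ± 5179 against 60752 ± 15710.5 (-1.40, adjusted p = 0.000855). Nkg7 fell by 1.46 (adjusted p = 0.000297), both near the T cell median. The members that rose were Lamp1, a lysosomal membrane protein (1.66, adjusted p = 0.000359), the cytokine Tnf (3169.8 ± 566 against 541 ± 194; 2.61, adjusted p = 0.000589) and the chemokine receptor Cx3cr1 (1.52, adjusted p = 0.00117). Of 23 oxidative stress and ferroptosis genes 10 rose (11 adjusted over the list alone; median 0.93, set test adjusted p = 0.00258, and 0.0467 with an estimated correlation). The smallest adjusted p were those of the ferritin genes Ftl1 (1.99, adjusted p = 2.32e-05) and Fth1 (2.31, adjusted p = 5.59e-05). Of 37 ribosomal protein genes 12 fell, 28 with quantile normalization, 22 with only the groups compared, 7 with library weights, and 6, 7 and 5 without double-negative replicates 1, 2 and 3 (22 adjusted over the list alone; median -0.51, set test adjusted p = 3.13e-16, and adjusted p = 0.298 with an estimated correlation).

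Over all genes, 1684 of 13000 tested were called, 1296 higher and 388 lower in double-positive cells, and edgeR called 993. Quantile normalization moved the median of all genes by -0.48, from 0.26 to -0.21, and the split to 978 higher and 940 lower. Among the largest rises, Itga5, an integrin chain, was at least 1493-fold and Abcc3, an organic anion transporter, at least 921-fold higher, while Saa3, an acute phase protein, stood at 11129 ± 10378 against 3.30 ± 1.48 (10.78, adjusted p = 6.07e-06). Among the largest falls was Cd7, a T and NK cell surface protein (609 ± 202 against 5473 ± 1912; -3.18, adjusted p = 0.000179).

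Libraries labelled as LepR single-positive were compared with double-negative ones, and Lepr stood at 10.5 ± 8.31 against 10.6 ± 4.25 (-0.21, adjusted p = 0.957). Saa3 rose from 3.30 ± 1.48 to 2374 ± 1231 (8.96, adjusted p = 0.000321) and Bst1, an ectoenzyme, from 3.44 ± 3.34 to 791 ± 261 (7.83, adjusted p = 0.000255). Cav2, caveolin 2, and Stil, a centriole protein, had no read in double-negative cells and were at least 164-fold and 159.7-fold higher. With only the groups compared these 4 calls were lost (adjusted p = 0.186 to 0.307), and 2 of 35 splits, the real one included, gave as many calls. Of 25 macrophage markers 2 rose, 5 without double-negative replicate 2 and 0 with library weights or only the groups compared (12 adjusted over the list alone). They were Spi1 (2289 ± 786 against 847 ± 89.4; 1.38, adjusted p = 0.0264) and Arg1 (3249.6 ± 2140.1 against 465 ± 133; 2.64, adjusted p = 0.0349). Both lost their calls with library weights and with only the groups compared. Spi1 lost its call without LepR single-positive replicate 3 (adjusted p = 0.0543), and Arg1 without double-negative replicate 2 (adjusted p = 0.0597) or LepR single-positive replicates 1 or 4 (adjusted p = 0.0565 and 0.0577), without a filter and with edgeR. The median of the macrophage list was 1.24, and 0.65 without double-negative replicate 3 (set test adjusted p = 2.34e-05, and adjusted p = 0.645 with an estimated correlation). The macrophage to T cell ratio was 0.451 ± 0.215 (SD, n = 4) in LepR single-positive libraries. Cd36 stood at 87.2 ± 152, with no read in double-negative cells (adjusted p = 0.399; called with DESeq2).

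None of 14 leptin and STAT3 target genes passed over all genes (3 at an unadjusted p under 0.05, 1 lower adjusted over the list alone), at a median of -0.42 (set test adjusted p = 0.00165, and adjusted p = 0.577 with an estimated correlation). Stat3 stood at 9004 ± 3100.2 against 19068 ± 5079.7 (-1.11, adjusted p = 0.129; called with DESeq2) and Socs3, a feedback inhibitor of the pathway, at 2023 ± 638 against 3786 ± 1439 (-0.87, adjusted p = 0.25). None of 37 ribosomal protein genes passed, over all genes or over the list alone (4 at an unadjusted p under 0.05). Their median of 0.30 came to 0.47 and 0.19 without LepR single-positive replicates 1 and 2 (set test adjusted p = 0.000368, lost with an estimated correlation, adjusted p = 0.703, and without LepR single-positive replicate 2, adjusted p = 0.0578).

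Of 13000 genes 54 were called, 44 higher and 10 lower, with 1923 at an unadjusted p under 0.05, and quantile normalization moved the median of all genes by -0.16. The count was 235 without double-negative replicate 1, 118 without double-negative replicate 2 and 85 without LepR single-positive replicate 2. Fitted on these 7 libraries alone, limma called 0 genes, with 1101 at an unadjusted p under 0.05, against 18 calls with edgeR and 873 with DESeq2.

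Libraries labelled as double-positive were compared last with those labelled as LepR single-positive. Cd36 stood at 1189 ± 796 against 87.2 ± 152 (log2 fold change 6.55, SE 1.59, adjusted p = 0.0162), a call lost with edgeR and DESeq2. Ifngr2 was higher (5046 ± 1432 against 503 ± 244; 3.40, adjusted p = 0.000669). Ifng fell like T cell markers (5429 ± 447 against 12341 ± 2413; -1.17, adjusted p = 0.000493). Of 25 macrophage markers 22 rose (24 adjusted over the list alone; median 2.97, set test adjusted p = 1.31e-21, and adjusted p = 0.0727 with an estimated correlation). Among them was Itgam, the CD11b integrin chain (18978 ± 5601 against 945 ± 422; 4.39, adjusted p = 5.25e-05). Of 16 T cell markers 14 fell, over all genes and over the list alone (median -1.27, set test adjusted p = 4.05e-18, and adjusted p = 0.0727 with an estimated correlation). Among them was Trac, a T cell receptor constant gene (15726 ± 2473 against 38152 ± 5829; -1.28, adjusted p = 0.000232). Of 32 type I interferon response genes 10 rose and 1 fell (17 and 2 adjusted over the list alone; median 1.26, set test adjusted p = 0.000358, and adjusted p = 0.181 with an estimated correlation). Irf7 stood at 7576 ± 3608 against 2055 ± 389 (1.77, adjusted p = 0.00347). The member that fell was Isg20, an exonuclease (-1.20, adjusted p = 0.0059). Lepr stood at 17.8 ± 30.5 against 10.5 ± 8.31 (-0.26, adjusted p = 0.91).

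Of 27 cytotoxic effector genes 4 rose and 10 fell (5 and 14 adjusted over the list alone; median -0.88, set test adjusted p = 5.94e-05, and adjusted p = 0.0727 with an estimated correlation). Nkg7 fell by 1.74 (adjusted p = 6.82e-05), while Lamp1 (2.10), Cx3cr1 (2.05), Tnf (1.57) and Zeb2 (1.76, adjusted p = 0.029) rose. Zeb2 lost its call without any double-positive replicate except the third or any LepR single-positive replicate except the second (adjusted p = 0.0541 to 0.084), and with edgeR. Of 37 ribosomal protein genes 36 fell (37 adjusted over the list alone; median -0.80, set test adjusted p = 8.17e-27, and adjusted p = 0.181 with an estimated correlation). Of 44 oxidative phosphorylation genes 13 fell and 1 rose (26 and 1 adjusted over the list alone; median -0.50, set test adjusted p = 2.51e-11, and adjusted p = 0.193 with an estimated correlation), such as Ndufa4 (-1.21, adjusted p = 0.00583). The 13 were 25 with quantile normalization, 8 without a filter, 5, 7 and 7 without double-positive replicates 2, 3 and 5, and 24, 5 and 5 without LepR single-positive replicates 1, 2 and 4. The one that rose was Sdha (0.53, adjusted p = 0.0478), a call lost without a filter, with quantile normalization, library weights and edgeR, and without any double-positive replicate or LepR single-positive replicates 1, 2 or 4 (adjusted p = 0.0551 to 0.131). In all, 1900 of 13000 genes were called, 1172 higher and 728 lower; quantile normalization moved the median of all genes by -0.41, from 0.20 to -0.21, and the split to 1035 higher and 1348 lower. The count was 1234 without double-positive replicate 2 and 1243 without LepR single-positive replicate 2.

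**Figure D3:**
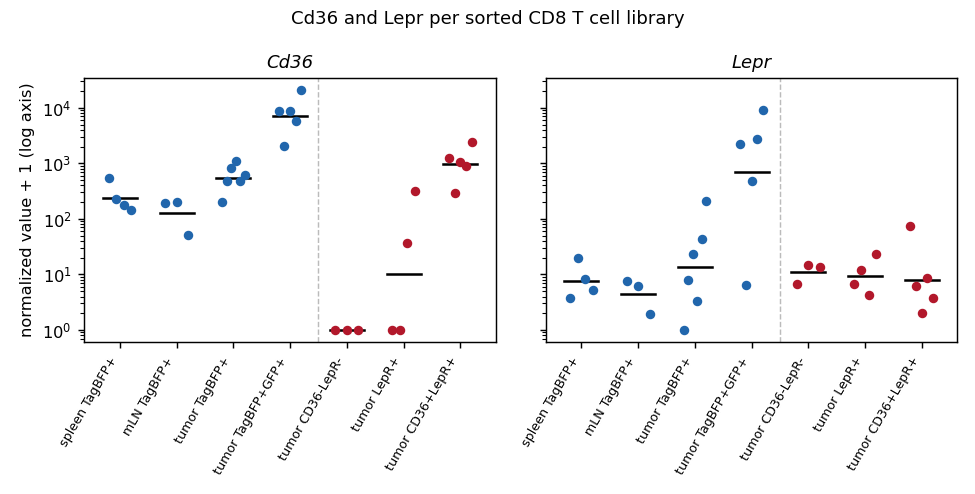
Normalized value + 1 of Cd36 (left) and Lepr (right) on a log axis in each library of the 7 CD8 T cell groups; points are libraries, horizontal bars are means on the log scale, and the dashed line parts the 2 separately normalized tables, whose levels are not to be compared. Cd36 is at 0 in the 3 double-negative libraries. Lepr is at 17.8 ± 30.5 (SD, n = 5) in CD36 and LepR double-positive cells.

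Genes called at a log2 fold change of at least 1 in TagBFP and GFP double-positive tumor cells were then followed in the wild-type sorts, which share no library with that table. Of the 40 genes higher there, 32 were measured. Of these, 13 rose and none fell in double-positive against double-negative cells (median 2.90, set test adjusted p = 6.83e-06, and 0.0327 with an estimated correlation). Against LepR single-positive cells 12 rose and none fell (median 1.93, adjusted p = 0.000109, and 0.0391 with an estimated correlation). Both counts include Cd36, a sort marker. In LepR single-positive against double-negative cells the median was 0.49 and 1 of the 32 rose (adjusted p = 0.0893, and 0.336 with an estimated correlation), a set that was called without LepR single-positive replicate 2 (median 0.81, adjusted p = 0.0347). Of the 18 genes lower there, 14 were measured and none of the 3 set tests was called (adjusted p = 0.762, 0.221 and 0.627); in the last, against LepR single-positive cells, the median was 0.09 while the test pointed down. The macrophage to T cell ratio was also higher in both double-positive groups, and a rise apart from it was not tested.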

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

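The tests of macrophage RNA in both tumor sorts and of Lepr were chosen after the result was seen. Those of scaling and other splits were chosen before. Libraries far from their group were sought among 199 sets of values, and 34 stood out. Sets with reads in 1 library alone always stand out, so no chance rate holds. Limits to the groups each comparison uses and to sets reaching the minimum value were set after the data were seen.

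In the tumor libraries of the reporter mice, T cell transcripts were low and macrophage transcripts high. The authors' scaling is argued against, since the T cell list's median against spleen was -4.54 after quantile normalization. A candidate is RNA of macrophages and monocytes that outweighs T cell RNA, which needs the T cell list to fall by about 1 factor. In single-positive libraries the list's log2 fold changes against spleen had an interquartile range of 0.624, but Cd8b1 fell further than Cd8a. Whether tumor T cells hold such transcripts was not tested.

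In CD36 and LepR double-positive libraries of wild-type tumors, macrophage transcripts were higher and T cell transcripts lower than in double-negative ones. The authors' scaling is argued against, with a median of the T cell list of -1.34 after quantile normalization. RNA of macrophages and monocytes added to T cell RNA may account for a fall of the T cell list by about 1 factor, since the interquartile range of its log2 fold changes was 0.285. Of the macrophage list, Ctss stood at 120397 ± 25186 and Arg1 at 29469 ± 16839.5 (SD, n = 5) there, although the sort was for CD8 T cells. A change of state within the sorted T cells was not tested.

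The Lepr transcript lay near the floor in cells sorted for LepR, at 10.5 ± 8.31 (SD, n = 4) in LepR single-positive and 17.8 ± 30.5 (SD, n = 5) in CD36 and LepR double-positive cells. Too little depth is argued against, since 3 reads came to at most 3.98 normalized units in these libraries. Reads lost in counting are argued against as well, since Lepr was above 100 in 4 TagBFP and GFP double-positive tumor libraries; that table was normalized separately, so this shows only that reads of Lepr were counted there. No biological explanation was tested.

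Other splits of the same samples into groups of the same sizes were fitted to ask whether chance gives as many calls, and the real split is counted among those as large. For GFP-high against GFP-negative cells, 1 of 35 splits gave as many as 2221, and the highest other gave 0. In double-positive against single-positive tumor cells of the reporter mice it was 1 of 100 drawn from 462 (60 against 12 in the highest other), and among the 32 splits that part all 5 pairs the highest other gave 2. Tumor against spleen gave 1 of 100 (6225 against 853), tumor against mLN 1 of 84 (5481 against 26) and mLN against spleen 1 of 35 (307 against 165). CD36 and LepR double-positive against double-negative cells gave 1 of 56 (1684 against 17) and against LepR single-positive cells 1 of 100 (1900 against 276). So few splits cannot exclude chance but make it unlikely in these 7, less so in mLN against spleen. Chance stays open for LepR single-positive against double-negative cells, at 2 of 35 (54 against 70).

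Among library measures, GFP-negative replicate 4 had 59.7 M reads while the others of its group had 19.3 to 22.7, and TagBFP and GFP double-positive replicate 5 had 76.5 M against 21.4 to 36.1. Spleen replicate 2 had a mean correlation of 0.806 with its group, and the ratio of macrophage to T cell values was 0.136 in spleen replicate 3 against 0.189 to 0.197 in the others.

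Single genes stood apart in 1 library as well, with normalized values as follows. In GFP-negative epithelial cells, Susd2 reached 75.3 and Slc5a12 17.4 in replicate 1, and Gdpd2 reached 16.4 and Egln3 106 in replicate 3, and in GFP-high cells Sst reached 252 in replicate 2. Ifng was 294 in double-positive replicate 5 of the reporter tumors. Tumor single-positive replicate 6 was high in Lepr (210.3) and Vsig4 (12.2) and low in C5ar1 (17461), Dab2 (14351), Clec5a (11157) and Msr1 (20660.5), 6 of the 34. Ggt1 was 57.6 in single-positive replicate 5 and Rapgef4 63.0 in replicate 1. Spleen replicate 3 was high in Dab2 (47.5), Clec5a (28.7), Zfp708 (18.2) and Gstt1 (13.7), and replicate 4 in Cd209b (16.5). Hemoglobin transcripts stood apart in spleen replicate 1: Hbb-bs at 156598, Hba-a2 at 100242 and Hba-a1 at 88365. In CD36 and LepR double-positive cells, Lepr was 72.2 in replicate 1, Taf15 43.8 and Cds1 1128 in replicate 2, P2ry2 1067 in replicate 3, and Ggt7 76.0 and Gpr55 26.3 in replicate 5. In LepR single-positive replicate 4, Cd36 was 314 and Ago1 1139.7.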

How the results depend on the processing

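The edgeR and DESeq2 tests, the settings of gene lists beyond the estimated correlation and those of genes named outside the rule were chosen after the data were seen, and the other alternatives before. For named genes, 7290 values kept their direction and side of the threshold, 520 lost the call, 91 gained it and 48 changed sign. For gene lists 1186 kept and 102 lost it, and of the counts and signature medians 198 did not change by this measure, 24 became weaker, 12 stronger and 3 reversed. The cause was not tested for any change given here. Depth limits genes of few reads, since 3 reads per library is the floor.

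In double-positive against single-positive tumor cells of the reporter mice (60 calls), 38 genes were called without a filter, 242 with library weights, 144 with only the groups compared, 263 with DESeq2 and 22 to 89 with 1 library left out. The replicate block by library name, which pairs these samples, gave 204, and the block by title 196. Beyond the changes given with the results, the pair block ended the calls of Grap2, Spn and Haao and added calls of Klrk1, Tgtp1, Pfkl, Alox5, Aif1, H2-Eb1, H2-Ab1 and H2-Aa. The adipocyte list had too few genes to test there. The pair block changed no other call of a named gene or of a list described.

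In mLN against spleen (307), 2 were called with only the groups compared (899 at an unadjusted p under 0.05), 880 with DESeq2 and 186 to 406 with 1 library left out. In CD36 and LepR double-positive against double-negative cells (1684), edgeR called 993. In LepR single-positive against double-negative cells (54), 31 were called with a pseudocount of 8, 23 with quantile normalization and 17 with library weights. With only the groups compared 0 were called by limma (1101 at an unadjusted p under 0.05), against 18 with edgeR, 873 with DESeq2 and 37 to 235 with 1 library left out. In double-positive against LepR single-positive cells (1900), 1234 to 2022 were called with 1 library left out. Those ranges were 1491 to 2362 for GFP-high cells, 5724 to 6322 for tumor against spleen, 4254 to 5331 for tumor against mLN and 1253 to 1799 for double-positive against double-negative cells.

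Outside the tumor reporter comparison the samples share only a number. The replicate block by library name gave 1866 calls in GFP-high cells, 3102 in tumor against spleen, 5172 in tumor against mLN and 1314 in double-positive against LepR single-positive cells. It gave 64 in double-positive against double-negative cells, where the block by title gave 158. By limma it gave 0 in mLN against spleen (914 at an unadjusted p under 0.05; 281 with edgeR and 880 with DESeq2, without a block). In LepR single-positive against double-negative cells limma gave 0 with either block (928 and 668 at an unadjusted p under 0.05; 18 and 873 with edgeR and DESeq2, without a block). In none of these 7 did every library correlate best with its own number, and in none did all pairs pass 0.1.

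The signature's higher set in LepR single-positive against double-negative cells was called with the mean filter (median 0.55), and its median lay between 0.26 and 0.81 with 1 library left out. The test of its lower set in double-positive against LepR single-positive cells, which was not called, turned direction with the mean filter (median 0.40), with quantile normalization (-0.20) and without LepR single-positive replicate 2 (range -0.23 to 0.43).

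Among called genes, Reg3b in GFP-high cells turned to -0.17 with quantile normalization. The other genes that changed sign had not been called. In double-positive against single-positive tumor cells, Ifngr1 ran from -0.19 to 0.0098 and Ifngr2 from -0.16 to 0.083 with 1 library left out, and Ifngr2 was 0.024 with the replicate block. In tumor against spleen, Ifng was -0.040 with quantile normalization, -0.25 with library weights, -0.18 with edgeR and -0.16 with DESeq2, and ran from -0.27 to 0.83 with 1 library left out. Lepr was -0.59 with the replicate block. In tumor against mLN, Ifng was -0.19, -0.12, -0.72 and -0.67 in the same order, -0.23 with the replicate block and -0.87 to 1.14 with 1 library left out. In mLN against spleen, library weights gave -0.12 for Ifng and -0.021 for Ifngr2. With 1 library left out Ifng ran from -0.88 to 1.13, Ifngr1 from -0.29 to 0.10 and Ifngr2 from -0.036 to 0.43.

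In CD36 and LepR double-positive against double-negative cells, Lepr was 0.76 with edgeR and 0.75 with DESeq2, and ran from -1.27 to 0.018 with 1 library left out. In LepR single-positive against double-negative cells, the replicate block gave -0.040 for Cd8a and -0.019 for Ifngr2. Ifngr2 was -0.016 with edgeR and -0.086 with DESeq2, and Lepr 0.078 with edgeR. With 1 library left out Cd8a ran from -0.040 to 0.20, Ifngr2 from -0.56 to 0.68 and Lepr from -0.64 to 0.17. In double-positive against LepR single-positive cells, Lepr was 0.016 with a pseudocount of 8, 0.041 with library weights, 0.68 with edgeR and 0.76 with DESeq2, and ran from -1.06 to 0.23 with 1 library left out.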

Other observations

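The lists described here were chosen after their results were seen. Tumor TagBFP single-positive libraries of the reporter mice also held more transcripts of other groups than spleen libraries did. Of 37 interferon gamma response genes 20 rose (21 adjusted over the list alone; median 1.02, limma set test adjusted p = 8.86e-05, and adjusted p = 0.505 with an estimated correlation), while 14 rose and 3 fell with quantile normalization. Cxcl9, a chemokine induced by interferon gamma, stood at 16444 ± 7439 against 27.6 ± 41.5 (SD, n = 6 and 4; log2 fold change 10.51, limma adjusted p = 3.29e-07). Of 24 unfolded protein response genes 17 rose, over all genes and over the list alone (median 1.45, set test adjusted p = 0.000174, and adjusted p = 0.0783 with an estimated correlation), while 14 rose and 2 fell with quantile normalization. Xbp1, a transcription factor of that response, stood at 20616 ± 3956 against 2415 ± 574 (3.10, limma adjusted p = 2.76e-08).

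Markers of other cells moved as well. Of 13 epithelial and carcinoma cell markers 8 rose in tumor against spleen, over all genes and over the list alone, with a median of 5.02 (3.56 with genes without a spleen read at their bound; set test adjusted p = 0.014, and adjusted p = 0.505 with an estimated correlation). Cdh1, E-cadherin, stood at 4821 ± 2083 against 139.5 ± 173 (6.81, limma adjusted p = 6.11e-05). Against the mLN, 9 of 16 B and plasma cell markers fell in tumor (10 adjusted over the list alone; median -2.96, set test adjusted p = 0.000173, and adjusted p = 0.327 with an estimated correlation), among them Cd79b, a B cell receptor chain, at 666 ± 190.1 against 4949 ± 3744 (-2.69, limma adjusted p = 6.47e-05).

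In CD36 and LepR double-positive against LepR single-positive tumor cells of wild-type mice, 8 of 24 unfolded protein response genes rose (10 adjusted over the list alone; median 0.68, set test adjusted p = 0.000799, and adjusted p = 0.193 with an estimated correlation). That count rested on few libraries: 5 rose without double-positive replicates 1 or 5, 4 without double-positive replicate 2 and 4 without LepR single-positive replicates 2 or 4. It was 5 without a filter, while 6 rose and 1 fell with quantile normalization. Xbp1 stood at 13728 ± 2018 against 6719 ± 885 (1.03, limma adjusted p = 0.000767). No explanation was tested for these values.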
